A study of Mus musculus with 15 samples.

How the data were processed

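The study measured gene expression on 15 1-colour Affymetrix whole-transcript mouse arrays, each hybridised with biotin-labelled target made from total RNA. The cells were mouse embryonic fibroblasts infected with retroviruses carrying Oct4, Sox2, Klf4 and c-Myc, the factors used to turn fibroblasts into induced pluripotent stem cells. RNA was taken at day 3 after infection from cultures in 5 media, with 3 biological repeats per medium.

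The deposited table holds log2 expression values made by the authors, 1 column per array and 1 value for each of 28853 probe sets, which are called probes here. RMA and Partek are named in the submitters' processing notes; their versions, settings and roles are not given in the sources used here. The log base is not stated in those sources and was taken from the range and shape of the values, so that fold changes on the log2 scale rest on that reading. Array medians over all probes ran from 5.04 to 5.16. No detection calls, hybridisation dates or genome build were in the sources used here, so no genome positions are given. The number of arrays limits the precision, and the median standard error of a log2 change between media was 0.114.

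A gene was 1 symbol. In the table, 21789 probes had 1 gene symbol, 1621 had several and 5443 had none; probes with several or none were left out of the gene tests. Symbols of 21698 probes were matched to current names through their Entrez identifiers with the mouse gene table of the GRCm38.p6 assembly. For the 999 genes with more than 1 probe the probe with the highest mean over all arrays was used. This left 19938 genes, with no filter on dim genes and no further normalization.

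All arrays entered 1 linear model with a mean for each medium, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3. The moderated test was 2-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes within each of 7 comparisons. A gene was called at an adjusted p below 0.05, and the words rose and fell are used only of called genes. The prior degrees of freedom of the spread came to 4.80. The fit was tested on simulated data with the measured means and spreads, in which 200 genes were shifted in the BMP4 group. It called 57.6% of the genes shifted by 0.5 on the log2 scale, 92.5% of those shifted by 1 and 100% of those shifted by 2. Of its 181 calls, 14 were unchanged genes.

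The comparisons, the test, the 28 gene lists, the rule for naming genes and the alternatives were chosen before the data were examined, except where a choice is said to have followed the data. The lists cover BMP targets, TGF-beta targets, epithelial genes, mesenchymal genes, fibroblast matrix genes, smooth muscle and SRF targets, immediate early genes, the reprogramming factors, pluripotency genes, LIF and STAT3 targets, cell cycle genes, p53 and senescence genes, inflammatory secretion, interferon response, cholesterol synthesis and SREBP targets, hypoxia and glycolysis, the unfolded protein response and ATF4, NRF2 targets, Wnt targets, osteogenic, chondrogenic and adipogenic genes, and markers of macrophages, endothelium, keratinocytes, skeletal muscle, neural and glial cells and mesendoderm. Of their 551 entries 519 were measured; the other 32 have no probe of their own and were not analysed here. Each list was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Members that passed were also counted with the adjustment made over the list alone. Lists can share members, such as Acta2 in the mesenchymal and the smooth muscle lists, so their results are not independent.

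Named genes followed a rule. For each of the 4 main comparisons (BMP4 with SF1, FBS with SF1, BMP4 plus Noggin with BMP4, and ES medium with SF1) it takes the 6 largest rises and falls among called genes whose arrays did not overlap and whose higher mean was above the median of all genes, up to 4 called members per list, and always Id1, Id2, Id3, Smad6, Smad7, Cdh1, Epcam, Snai1, Snai2, Nanog, Pou5f1, Sox2, Klf4 and Myc. For each of the 3 other comparisons it takes the 3 largest rises and falls and, in list summaries, the genes always named. Of a list with no called member, up to 2 with the smallest p are named as not passing.

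The overlap of the BMP4 and serum responses and the share of the BMP4 response that Noggin turned back were counted beside simulations, 100 each, in which groups without a difference shared the same control arrays, and others, chosen after seeing the data, in which the FBS or Noggin response was shuffled over genes of like mean expression. Alternatives were a replicate block, a fit of only the groups compared, an intensity trend with robust spread, no moderation of the spread, array weights, quantile normalization, median centring, filters on dim genes (above the median on 3 arrays, or above the 25th percentile), the mean over the probes of a gene, every probe tested, a stricter adjusted p of 0.01, a 2-fold minimum, an estimated correlation for lists, and each array left out in turn. The interquartile range of each array as a covariate, and FBS replicates 1 and 3 taken as 1 sample, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.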

Results

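Expression of 19938 genes was measured in mouse embryonic fibroblasts 3 days after infection with the reprogramming retroviruses. The cultures were kept in a serum-free medium for induced pluripotent stem cells (iPS-SF1, called SF1 here), in SF1 with the growth factor BMP4, in SF1 with BMP4 and its secreted antagonist Noggin, in SF1 with fetal bovine serum (FBS), or in a standard embryonic stem (ES) cell medium. Each medium had 3 arrays, and levels are given as mean ± SD of the log2 value (n = 3). Genes are identified by symbol and the array's probe number, for example Id1 (10477169), Cdh1 (10575052), Thbs1 (10474700), Nr0b1 (10600707) and Pou5f1 (10444853). The median gene had a log2 value of 5.37.

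Media set the arrays apart. The first principal component held 41.1% of the variance, and on it cultures with BMP4 plus Noggin scored 28.6 to 29.1, SF1 22.7 to 23.4, FBS -5.68 to -5.21, BMP4 -20.5 to -19.2 and ES medium -28.0 to -23.6. The second component, with 14.1%, set FBS apart at 23.5 to 24.

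**Figure D1:**
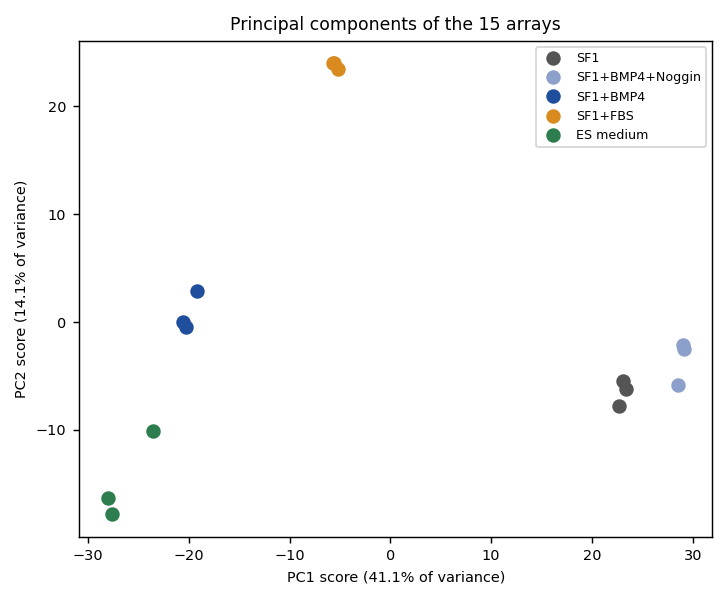
Scores of the 15 arrays on the first (x axis) and second (y axis) principal component of the log2 values, 1 point per array and 1 colour per medium. The arrays of each medium lie together, with SF1 at 22.7 to 23.4 and BMP4 at -20.5 to -19.2 on the first component.

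Of the reprogramming factors, Pou5f1, which encodes Oct4, was at 12.31 ± 0.04 in SF1 and 11.84 ± 0.09 in ES medium, Klf4 at 8.24 ± 0.09 and 8.60 ± 0.05, and Myc at 9.28 ± 0.08 and 9.51 ± 0.09. The value of Sox2 was near that of the median gene, 5.08 ± 0.21 in SF1 and 5.12 ± 0.10 in ES medium. Pou5f1 fell in ES medium (-0.46) and with BMP4 (-0.33), and Myc rose in ES medium (0.23). The call of Myc ended with median centring and without any 1 of SF1 replicates 1, 2 and 3 or ES medium replicates 2 and 3. The files do not separate the retroviral from the cells' own transcripts. Of the 4 factors, 1 also rose and 2 fell when Noggin was added to BMP4, 1 rose with FBS against SF1 and 1 fell in ES medium against FBS. As a list of 4, the factors were not called in any of the 7 comparisons, with adjusted p in limma's camera from 0.386 to 0.795. Nanog, a pluripotency gene of the cells' own genome, was at 5.23 ± 0.13 in SF1, 5.22 ± 0.31 with BMP4 and 5.06 ± 0.06 in ES medium, and did not pass in the comparisons of BMP4, FBS or ES medium with SF1 or of Noggin with BMP4.

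BMP4 added to SF1 raised genes of BMP signalling, epithelial genes and matrix genes together. Id1, Id2 and Id3, direct targets of BMP signalling that block differentiation factors, rose from 5.91 ± 0.19, 4.92 ± 0.13 and 5.08 ± 0.14 to 7.44 ± 0.13, 7.19 ± 0.23 and 7.04 ± 0.18 (log2 changes 1.53, 2.27 and 1.96; SD, n = 3). Cdh1, which encodes the epithelial adhesion protein E-cadherin, rose from 5.06 ± 0.09 to 6.70 ± 0.02, and Epcam, another epithelial adhesion gene, from 6.08 ± 0.16 to 7.18 ± 0.09. The matrix gene Thbs1 rose from 7.26 ± 0.10 to 11.22 ± 0.05, while Nr0b1, a nuclear receptor gene of the ES cell network, fell from 9.84 ± 0.01 to 7.33 ± 0.04. The largest rises on the log2 scale were those of Lipf (4.89), Gpr165 (4.08), Gpr50 (4.07), Akr1c14 (4.02), Thbs1 (3.96) and Rgs5 (3.68), which encode a gastric lipase, orphan receptors, an aldo-keto reductase, thrombospondin and a regulator of G-protein signalling. The largest falls were those of 4930550L24Rik (-2.62), Nr0b1 (-2.51), Bnc2 (-2.21), Crmp1 (-2.18), Npr3 (-1.85) and Prkcb (-1.84).

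Of 23 BMP target genes, 17 rose and 6 did not pass (19 rose adjusted over the list alone). Examples were Smad6 (1.22) and Smad7 (1.25), which encode inhibitory Smads, and Gata2 (1.38), at a median of 0.78 for the list (adjusted p = 9.5e-17 in limma's camera). Of 18 TGF-beta target genes, 13 rose and 5 did not pass (14 rose adjusted over the list alone). Ccn2 (2.65), Postn (1.72), Edn1 (1.49) and Skil (1.43) were among them, and the median log2 change of the list was 0.65 (adjusted p = 7.8e-13 in limma's camera). Of 24 epithelial genes, 13 rose, 1 fell and 10 did not pass (14 rose and 1 fell adjusted over the list alone). The splicing regulator gene Esrp1 (3.25), the keratin gene Krt19 (2.14) and the desmosome gene Dsp (1.29) were examples, and the list had a median log2 change of 0.52 (adjusted p = 3.1e-10 in limma's camera). The member that fell, Elf3 (-0.43), was named after its value was seen. Of 14 keratinocyte markers, 7 rose, 1 fell and 6 did not pass (10 rose and 1 fell adjusted over the list alone). Examples were the basal keratin gene Krt14 (2.11) and the integrin gene Itga6 (1.48), at a median of 0.61 for the list (adjusted p = 3.2e-07 in limma's camera).

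Mesenchymal and matrix genes rose in the same cultures. Of 24 mesenchymal genes, 11 rose, 2 fell and 11 did not pass (14 rose and 2 fell adjusted over the list alone). The smooth muscle actin gene Acta2 (2.06) and the cadherin genes Cdh11 (1.67) and Cdh2 (1.27) were among them, and the median log2 change of the list was 0.27 (adjusted p = 6.0e-07 in limma's camera). Snai1 and Snai2, transcription factor genes of the epithelial to mesenchymal transition, had log2 changes of -0.22 and 0.14 and did not pass (adjusted p = 0.383 and 0.478 in limma). Of 23 fibroblast matrix genes, 15 rose, 3 fell and 5 did not pass (15 rose and 3 fell adjusted over the list alone). Fbln5 (2.36), Col6a1 (1.98) and Sparc (1.58) were examples, and the list had a median log2 change of 0.75 (adjusted p = 3.8e-11 in limma's camera). The 3 that fell, Dcn (-0.72), Col3a1 (-0.53) and Fbln2 (-0.33), were named after their values were seen, and the call of Fbln2 ended without BMP4 replicate 3. Of 18 smooth muscle and SRF target genes, many of which encode contractile proteins, 10 rose and 8 did not pass (12 rose adjusted over the list alone). Examples were Cnn2 (1.79), Tagln (1.29) and Cald1 (0.95), at a median of 0.61 for the list (adjusted p = 1.4e-10 in limma's camera). Of 16 immediate early genes, 12 rose and 4 did not pass (14 rose adjusted over the list alone). Ccn1 (2.25), Dusp1 (1.49), Fos (0.89) and Egr1 (0.89) were among them, and the median log2 change of the list was 0.56 (adjusted p = 1.0e-11 in limma's camera).

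Of 31 cell cycle genes, 14 fell and 17 did not pass (22 fell adjusted over the list alone). Mki67 (-0.52), Bub1 (-0.52), Tyms (-0.44) and Mcm2 (-0.42) were examples, and the list had a median log2 change of -0.26 (adjusted p = 2.3e-07 in limma's camera, and adjusted p = 0.103 with an estimated correlation). The calls of Mki67 and Bub1 ended without any 1 of BMP4 replicates 1 and 2 and SF1 replicate 1, and that of Mki67 also without SF1 replicate 3. Of 18 p53 and senescence genes, 10 rose and 8 did not pass (12 rose and 1 fell adjusted over the list alone). Examples were Perp (0.76), Cdkn2b (0.70) and Mdm2 (0.46), at a median of 0.31 for the list (adjusted p = 6.1e-05 in limma's camera). The pluripotency list was not called in the main fit. Of 28 pluripotency genes, 2 rose, 7 fell and 19 did not pass (2 rose and 7 fell adjusted over the list alone). Lin28b (-1.09), Fbxo15 (-0.95) and Alpl (-0.66) were among them, and the median log2 change of the list was -0.06 (adjusted p = 0.0615 in limma's camera). It was called lower without BMP4 replicate 1 (median log2 change -0.11) and without SF1 replicate 1 (-0.15). In all, 3545 genes were called, 1842 higher and 1703 lower, and 415 of them changed at least 2-fold, 329 higher and 86 lower. The adjusted p of Thbs1 was 1.4e-13, that of Id3 1.0e-08 and that of Cdh1 9.3e-09 in limma. Small nucleolar RNAs, a class of short transcripts looked at only after the values were seen, were lower with BMP4 in 14 of 51 genes (median log2 change -0.24).

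**Figure D2:**
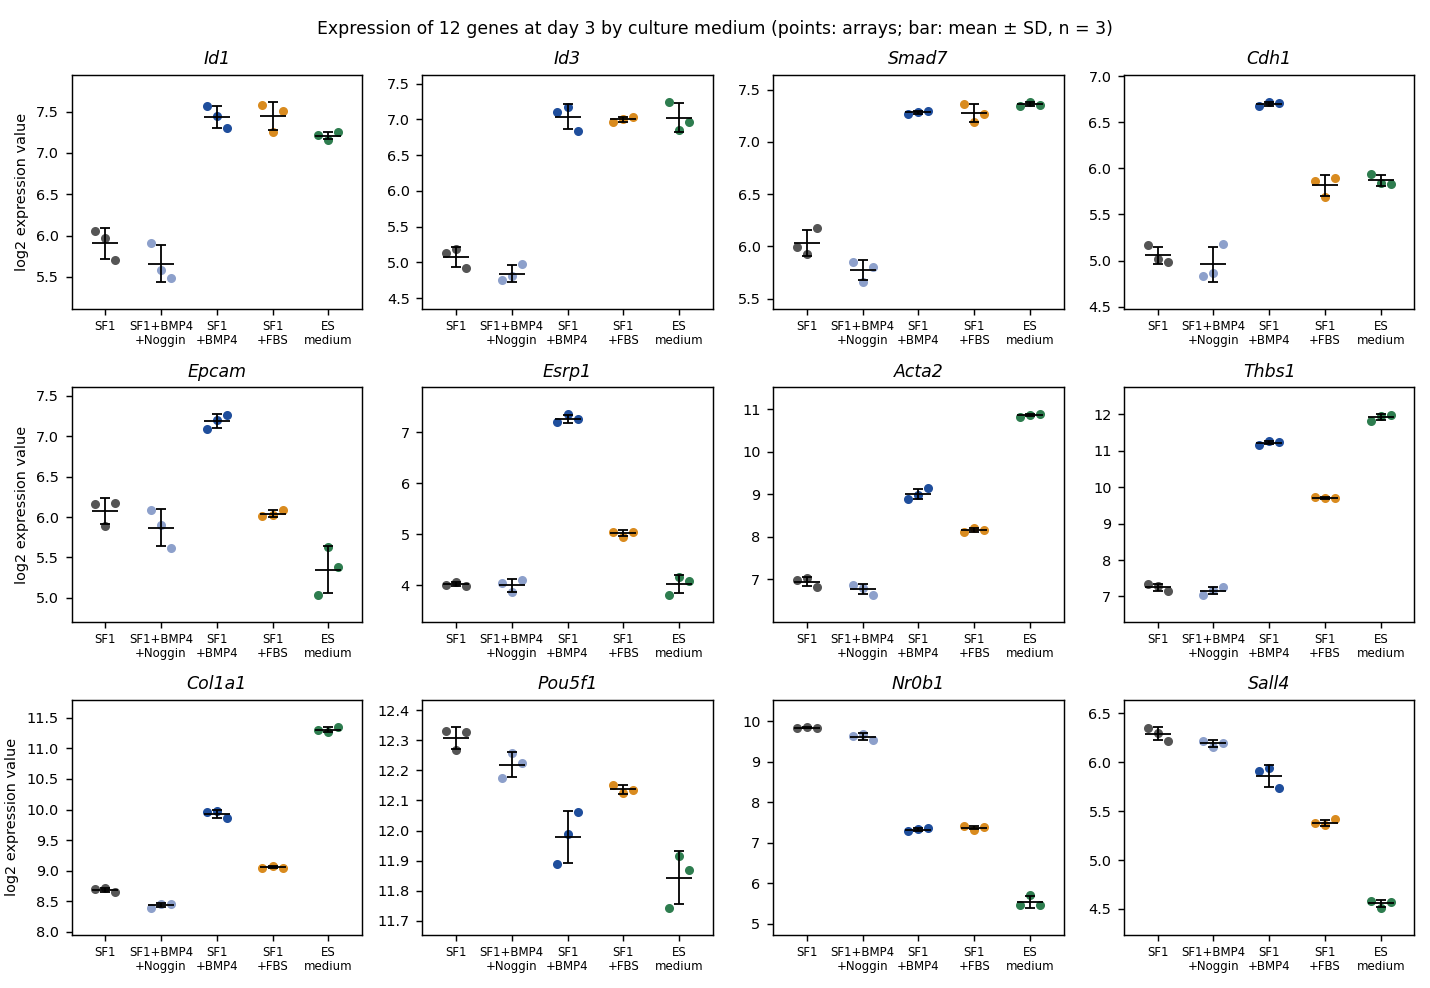
Log2 expression value (y axis) of 12 genes in the 5 media (x axis); points are arrays and bars are the mean ± SD (n = 3). Id1 is at 5.91 ± 0.19 in SF1, 7.44 ± 0.13 with BMP4 and 5.66 ± 0.22 with BMP4 plus Noggin.

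Noggin, which binds BMP proteins outside the cell, turned most of the BMP4 response back. Id1, Id2 and Id3 fell from 7.44 ± 0.13, 7.19 ± 0.23 and 7.04 ± 0.18 to 5.66 ± 0.22, 4.42 ± 0.17 and 4.84 ± 0.12 (log2 changes -1.78, -2.78 and -2.19; SD, n = 3). Cdh1 fell to 4.96 ± 0.19, Epcam to 5.87 ± 0.23 and Thbs1 to 7.16 ± 0.10, while Nr0b1 rose to 9.62 ± 0.08. Of the 3545 genes called with BMP4, 2803 (79.1%) were called in the opposite direction with Noggin. Independent lists would share 425, and simulations in which Noggin had no effect, and so almost no calls, gave at most 0. With the measured Noggin response shuffled over genes of like expression and the BMP4 arrays still shared, simulations gave a mean of 1169 and at most 1254. Those simulations added noise to measured means that already hold noise, so they can call more genes than the data. Their totals of calls are not given here, so their excess over independent lists cannot be assigned. Part of the count may still come from the shared arrays, or from both responses lying at like expression levels. These were not told apart by a simulation without shared arrays. Of the 415 genes changed at least 2-fold by BMP4, 414 turned back, and the median percent of the log2 change left was -2.30 (quartiles -12.1 and 6.35).

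The largest falls with Noggin were those of Lipf (-4.53), Gpr50 (-4.14), Akr1c14 (-4.07), Thbs1 (-4.06), Gpr165 (-3.86) and Rgs5 (-3.82), and the largest rises those of 4930550L24Rik (2.76), Nr0b1 (2.29), Crmp1 (2.23), Bnc2 (2.16), Aldh1a1 (2.16) and Prkcb (2.03); Aldh1a1 encodes an enzyme of retinoic acid synthesis. Among the 23 BMP target genes, 17 fell and 6 did not pass (18 fell adjusted over the list alone). Smad6 (-1.17), Smad7 (-1.51) and Gata2 (-1.62) were examples, and the list had a median log2 change of -0.74 (adjusted p = 1.1e-13 in limma's camera). Among the 18 TGF-beta target genes, 15 fell and 3 did not pass (16 fell adjusted over the list alone). Examples were Ccn2 (-2.60), Edn1 (-1.77) and Postn (-1.74), at a median of -0.71 for the list (adjusted p = 1.1e-13 in limma's camera). Among the 24 epithelial genes, 14 fell and 10 did not pass (14 fell adjusted over the list alone). Esrp1 (-3.27), Krt19 (-2.30) and Dsp (-1.34) were among them, and the median log2 change of the list was -0.39 (adjusted p = 3.4e-09 in limma's camera). Among the 14 keratinocyte markers, 1 rose, 7 fell and 6 did not pass (1 rose and 8 fell adjusted over the list alone). Krt14 (-2.02) and Itga6 (-1.77) were examples, and the list had a median log2 change of -0.42 (adjusted p = 4.4e-05 in limma's camera).

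Among the 24 mesenchymal genes, 2 rose, 17 fell and 5 did not pass (2 rose and 17 fell adjusted over the list alone). Examples were Acta2 (-2.24), Cdh11 (-1.76) and Tgfb1 (-1.39), at a median of -0.44 for the list (adjusted p = 3.3e-09 in limma's camera). Snai2 fell by 0.38, a call that ended without BMP4 replicate 2 or 3 or Noggin replicate 1 or 2. Among the 23 fibroblast matrix genes, 2 rose, 15 fell and 6 did not pass (3 rose and 15 fell adjusted over the list alone). Fbln5 (-2.75), Col6a1 (-2.19) and Sparc (-1.83) were among them, and the median log2 change of the list was -0.82 (adjusted p = 4.4e-12 in limma's camera). Among the 18 smooth muscle and SRF target genes, 13 fell and 5 did not pass (14 fell adjusted over the list alone). Cnn2 (-1.92) and Tagln (-1.42) were examples, and the list had a median log2 change of -0.71 (adjusted p = 1.4e-11 in limma's camera). Among the 16 immediate early genes, 11 fell and 5 did not pass (11 fell adjusted over the list alone). Examples were Ccn1 (-2.53) and Dusp1 (-1.55), at a median of -0.71 for the list (adjusted p = 1.3e-08 in limma's camera). Among the 18 p53 and senescence genes, 1 rose, 9 fell and 8 did not pass (1 rose and 11 fell adjusted over the list alone). Their median log2 change was -0.26 (adjusted p = 3.3e-04 in limma's camera). Among the 31 cell cycle genes, 14 rose, 1 fell and 16 did not pass (15 rose and 1 fell adjusted over the list alone). Bub1 (0.65), Pcna (0.46) and Mcm5 (0.43) were among them, and the median log2 change of the list was 0.25 (adjusted p = 8.9e-05 in limma's camera, and adjusted p = 0.233 with an estimated correlation). Counts came to 4772 called genes, 2221 higher and 2551 lower, with 511 at least 2-fold (101 higher and 410 lower). The adjusted p of Id2 was 5.2e-09 and that of Lipf 2.9e-11 in limma. Small nucleolar RNAs rose in 44 of 51 genes (median log2 change 0.67), from a median level of 6.20 ± 0.10 with BMP4 to 7.06 ± 0.12 with Noggin. Short mRNAs of ribosomal proteins and the respiratory chain moved the same way (median log2 change 0.21).

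Compared with plain SF1, cultures with BMP4 plus Noggin differed in fewer genes than those with BMP4 alone. Id1, Id2 and Id3 were at 5.66 ± 0.22, 4.42 ± 0.17 and 4.84 ± 0.12 with Noggin and at 5.91 ± 0.19, 4.92 ± 0.13 and 5.08 ± 0.14 in SF1, with none of the 3 passing. The largest rises were of short noncoding RNA genes, a 5S ribosomal RNA and small nucleolar RNAs, n-R5s136 (1.13), Snora16a (1.01) and Snord15a (0.86). The largest falls were those of the linker histone gene H1f2 (-0.95), Bex4 (-0.75) and the homeobox gene Hoxb2 (-0.70). The calls of n-R5s136 and Hoxb2 ended without any 1 of the 6 arrays, and that of Bex4 without any but SF1 replicate 3; all 3 also ended with the array spread covariate, with log2 changes still at 1.09, -0.63 and -0.70 for n-R5s136, Bex4 and Hoxb2, and those of n-R5s136 and Bex4 with median centring. Small nucleolar RNAs rose in 16 of 51 genes (median log2 change 0.49), from 6.47 ± 0.13 to 7.06 ± 0.12 at their median. BMP targets were not called as a list (median log2 change -0.05, adjusted p = 0.551 in limma's camera). Of 24 mesenchymal genes, 1 fell and 23 did not pass (2 fell adjusted over the list alone), with a median log2 change of -0.16 (adjusted p = 0.00185 in limma's camera, and adjusted p = 0.423 with an estimated correlation). Of 23 fibroblast matrix genes, 1 fell and 22 did not pass (1 rose and 6 fell adjusted over the list alone), with a median log2 change of -0.15 (adjusted p = 0.00115 in limma's camera, and adjusted p = 0.423 with an estimated correlation). Of 18 smooth muscle and SRF target genes, 1 fell and 17 did not pass (1 fell adjusted over the list alone), with a median log2 change of -0.12 (adjusted p = 0.0119 in limma's camera, and adjusted p = 0.423 with an estimated correlation). Of 24 hypoxia and glycolysis genes, none passed in limma (8 at an unadjusted p under 0.05), with a median log2 change of -0.12 (adjusted p = 0.00728 in limma's camera, and adjusted p = 0.625 with an estimated correlation). In all, 318 genes were called in limma, 90 higher and 228 lower, 2 of them at least 2-fold. It was 359 genes with quantile normalization (281 of them the same), 289 with the mean over probes and 301 with array weights. The count depended on single arrays, with 15 without Noggin replicate 1, 19 without Noggin replicate 3, and 33, 26 and 70 without SF1 replicates 1, 2 and 3. It came to 79 with the spread of each array as a covariate, chosen after seeing the data, and to 0 in a limma fit of these arrays alone (2509 at an unadjusted p under 0.05). Other settings raised the count, to 971 and 518 with the filters at the median and the 25th percentile, 873 with an intensity trend and robust spread, 630 without moderation and 609 with every probe, and median centring lowered it to 128.

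Serum added to SF1 raised the Id genes and Cdh1, while Epcam did not pass. Id1, Id2 and Id3 rose to 7.45 ± 0.17, 6.43 ± 0.31 and 7.01 ± 0.03 (SD, n = 3; log2 change 1.92 for Id3), and Cdh1 to 5.82 ± 0.11 (0.76). Epcam was at 6.04 ± 0.04 in FBS and 6.08 ± 0.16 in SF1 (adjusted p = 0.914 in limma). The largest rises were those of Akr1c14 (3.17), Ccn1 (3.03), Anxa10 (2.52), Rgs5 (2.46), Thbs1 (2.44) and Ptgs2 (2.37); Ccn1 encodes a matrix protein induced by growth factors and Ptgs2 the inducible cyclooxygenase. The largest falls were those of Nr0b1 (-2.47), Crmp1 (-2.43), 4930550L24Rik (-2.13), Slc38a5 (-1.82), Slain1 (-1.80) and Bnc2 (-1.78), of which Slc38a5 encodes an amino acid transporter.

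Of 16 immediate early genes, which growth factors induce within minutes, 12 rose and 4 did not pass (12 rose adjusted over the list alone). Examples were Dusp1 (1.99), Nr4a1 (1.24) and Fos (1.21), at a median of 0.71 for the list (adjusted p = 4.4e-13 in limma's camera). Among the 18 smooth muscle and SRF target genes, 11 rose, 1 fell and 6 did not pass (11 rose and 1 fell adjusted over the list alone). Cnn2 (1.69), Acta2 (1.21) and Cald1 (0.91) were among them, and the median log2 change of the list was 0.37 (adjusted p = 3.9e-07 in limma's camera). Of 23 BMP target genes, 10 rose and 13 did not pass (11 rose adjusted over the list alone). Smad6 (0.72) and Smad7 (1.24) were examples, and the list had a median log2 change of 0.27 (adjusted p = 7.2e-08 in limma's camera). Among the 18 p53 and senescence genes, 12 rose and 6 did not pass (13 rose adjusted over the list alone). Examples were the death receptor gene Fas (1.23) and Perp (1.00) and Mdm2 (0.81), at a median of 0.39 for the list (adjusted p = 5.1e-08 in limma's camera). Of 25 cholesterol synthesis and SREBP target genes, 17 fell and 8 did not pass (19 fell adjusted over the list alone). Fasn (-0.80), Idi1 (-0.66) and Sqle (-0.64) were among them, and the median log2 change of the list was -0.33 (adjusted p = 8.2e-11 in limma's camera). Of 18 TGF-beta target genes, 9 rose, 1 fell and 8 did not pass (9 rose and 1 fell adjusted over the list alone). Ccn2 (1.82) and Edn1 (1.61) were examples, and the list had a median log2 change of 0.32 (adjusted p = 7.3e-05 in limma's camera, and adjusted p = 0.0708 with an estimated correlation).

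Among the 24 hypoxia and glycolysis genes, 16 rose and 8 did not pass (16 rose adjusted over the list alone). Examples were P4ha2 (0.90), Aldoc (0.89) and Slc2a1 (0.70), at a median of 0.36 for the list (adjusted p = 8.1e-10 in limma's camera, and adjusted p = 0.0708 with an estimated correlation). Of 24 epithelial genes, 8 rose, 1 fell and 15 did not pass (9 rose and 1 fell adjusted over the list alone). Krt19 (2.17), Esrp1 (1.00) and Krt18 (0.81) were among them, and the median log2 change of the list was 0.04 (adjusted p = 0.0112 in limma's camera, and adjusted p = 0.0835 with an estimated correlation). Of 14 keratinocyte markers, 4 rose, 1 fell and 9 did not pass (6 rose and 2 fell adjusted over the list alone). Itga6 (1.39) and Krt14 (1.38) were examples, and the list had a median log2 change of 0.24 (adjusted p = 0.0112 in limma's camera, and adjusted p = 0.0835 with an estimated correlation). Among the 24 mesenchymal genes, 10 rose, 2 fell and 12 did not pass (10 rose and 2 fell adjusted over the list alone). Examples were Tgfb3 (0.84) and Mmp3 (-1.03), at a median of 0.20 for the list (adjusted p = 0.00144 in limma's camera, and adjusted p = 0.124 with an estimated correlation). Among the 23 fibroblast matrix genes, 12 rose, 5 fell and 6 did not pass (12 rose and 5 fell adjusted over the list alone). Fbln5 (1.38) and Dcn (-1.02) were among them, and the median log2 change of the list was 0.30 (adjusted p = 3.2e-04 in limma's camera, and adjusted p = 0.10 with an estimated correlation). Of 31 cell cycle genes, 1 rose, 13 fell and 17 did not pass (1 rose and 14 fell adjusted over the list alone). The cyclin E genes Ccne2 (-1.09) and Ccne1 (-0.97) were examples, and the list had a median log2 change of -0.24 (adjusted p = 3.2e-06 in limma's camera, and adjusted p = 0.117 with an estimated correlation). Among the 28 pluripotency genes, 2 rose, 4 fell and 22 did not pass (2 rose and 4 fell adjusted over the list alone). Examples were Sall4 (-0.91) and Alpl (-0.82), at a median of -0.12 for the list (adjusted p = 0.0255 in limma's camera, and adjusted p = 0.108 with an estimated correlation). The pluripotency call ended with either filter and without SF1 replicate 2. In all, 4229 genes were called, 1901 higher and 2328 lower, with 248 at least 2-fold (195 higher and 53 lower). Small nucleolar RNAs rose in 10 and fell in 5 of 51 genes. FBS replicates 1 and 3 lay closer to each other than any other pair of repeats, with an SD of their difference of 0.0787 over genes above the median, against 0.130 to 0.241 for other pairs. With both taken as 1 sample, a choice made after seeing the data, 3199 genes were called.

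Many of the genes called with BMP4 were also called with serum. Called in the same direction by both against SF1 were 1947 genes (54.9% of those called with BMP4), 1043 higher and 904 lower, and 74 went in opposite directions. Independent lists would share 176 higher and 199 lower genes, and simulated groups without a change that shared the SF1 arrays gave at most 0, as groups without effects have almost no calls. With the measured FBS response shuffled over genes of like expression and the SF1 arrays still shared, simulations gave a mean of 1105 and at most 1203. Those simulations added noise to measured means that already hold noise, so they can call more genes than the data. Their totals of calls are not given here, so their excess over independent lists cannot be assigned. Part of the overlap may still come from the shared SF1 arrays, or from both responses lying at like expression levels. No simulation without shared arrays was run to tell these apart. Without shared arrays, BMP4 minus BMP4 plus Noggin correlated with FBS minus SF1 at r = 0.510 across genes, which are not independent replicates. Thbs1, Akr1c14, Krt19 and Ccn1 rose with FBS and fell when Noggin was added to BMP4, while Epcam fell with Noggin and did not pass with FBS.

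**Figure D3:**
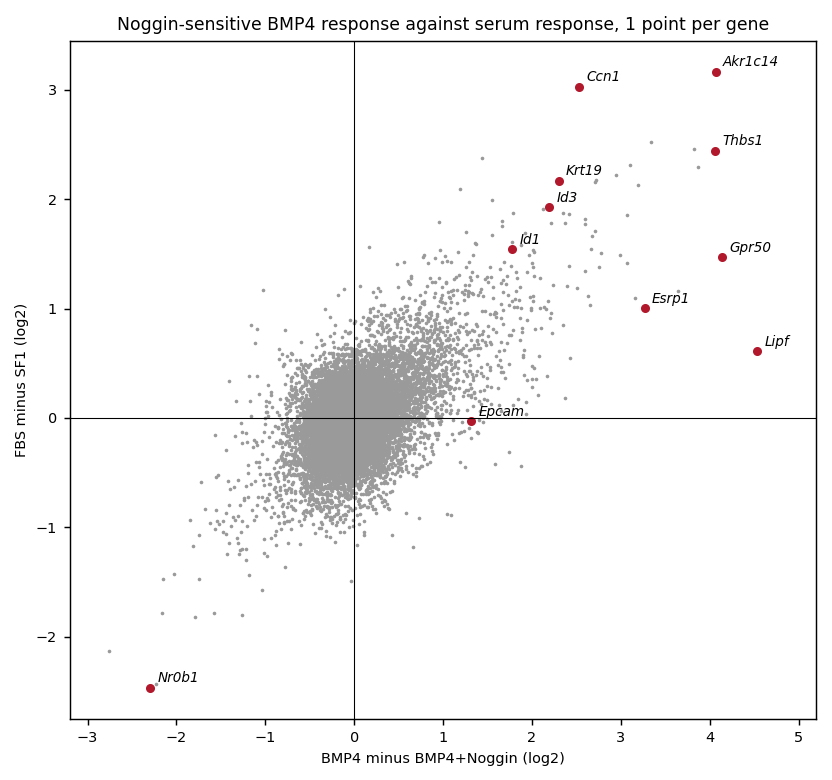
Difference of BMP4 minus BMP4 plus Noggin (x axis, log2) against FBS minus SF1 (y axis, log2), 1 point per gene, with 11 named genes in red; no array is used on both axes. The correlation across genes is r = 0.510.

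Set directly against serum, cultures with BMP4 had higher levels of epithelial genes and of cholesterol synthesis and SREBP target genes. Cdh1 was at 6.70 ± 0.02 with BMP4 and 5.82 ± 0.11 with FBS (log2 change 0.89; SD, n = 3), and Epcam at 7.18 ± 0.09 and 6.04 ± 0.04 (1.14). The largest rises were those of Lipf (4.28), Gpr50 (2.60) and Rgs4 (2.48), and falls among the largest were those of the thioredoxin-binding gene Txnip (-1.44) and the apolipoprotein gene Apod (-1.43). Among the 24 epithelial genes, 10 rose and 14 did not pass (12 rose and 1 fell adjusted over the list alone), with a median log2 change of 0.32 (adjusted p = 1.3e-06 in limma's camera). Among the 23 BMP target genes, 10 rose and 13 did not pass (12 rose adjusted over the list alone). Id2 (0.77) and Smad6 (0.50) were examples, and the list had a median log2 change of 0.33 (adjusted p = 5.1e-05 in limma's camera). The call of Smad6 ended without BMP4 replicate 3 or FBS replicate 3. Among the 25 cholesterol synthesis and SREBP target genes, 18 rose and 7 did not pass (18 rose adjusted over the list alone). The median log2 change was 0.39 (adjusted p = 3.6e-13 in limma's camera). Against SF1 this list was called lower with FBS and was not called with BMP4. There 4 members rose and 2 fell with BMP4 (median log2 change -0.004, adjusted p = 0.788 in limma's camera). Of 23 fibroblast matrix genes, 13 rose and 10 did not pass (15 rose adjusted over the list alone), with a median log2 change of 0.30 (adjusted p = 8.0e-12 in limma's camera). Of 24 hypoxia and glycolysis genes, 12 fell and 12 did not pass (14 fell adjusted over the list alone), with a median log2 change of -0.30 (adjusted p = 1.8e-07 in limma's camera, and adjusted p = 0.10 with an estimated correlation). Against SF1 this list was called higher with FBS at the preset correlation. With BMP4 it was not called against SF1 (median log2 change 0.04, adjusted p = 0.263 in limma's camera). Among the 16 immediate early genes, 1 rose, 6 fell and 9 did not pass (1 rose and 6 fell adjusted over the list alone), with a median log2 change of -0.15 (adjusted p = 0.0130 in limma's camera, and adjusted p = 0.0607 with an estimated correlation). Of 18 p53 and senescence genes, 1 rose, 5 fell and 12 did not pass (1 rose and 5 fell adjusted over the list alone), with a median log2 change of -0.11 (adjusted p = 0.0156 in limma's camera, and adjusted p = 0.10 with an estimated correlation). Among the 18 TGF-beta target genes, 9 rose and 9 did not pass (10 rose adjusted over the list alone), with a median log2 change of 0.26 (adjusted p = 1.0e-05 in limma's camera, and adjusted p = 0.0552 with an estimated correlation). Small nucleolar RNAs fell in 25 of 51 genes (median log2 change -0.43). Limma called 3155 genes, 1797 higher and 1358 lower, with 144 at least 2-fold. The count was 2096 without BMP4 replicate 2, 2041 without FBS replicate 3, 2076 with FBS replicates 1 and 3 as 1 sample and 6482 with array weights.

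In standard ES medium matrix and contractile genes were far above their levels in SF1, while cholesterol synthesis and SREBP target genes were below them. Acta2, the smooth muscle actin gene, rose from 6.95 ± 0.12 to 10.86 ± 0.02 and Thbs1 to 11.91 ± 0.08 (log2 changes 3.91 and 4.65; SD, n = 3). Nr0b1 fell to 5.54 ± 0.14 (-4.30). Id1, Id2 and Id3 rose to 7.21 ± 0.04, 6.73 ± 0.21 and 7.02 ± 0.20, Cdh1 rose to 5.87 ± 0.06, and Epcam fell to 5.35 ± 0.29, with Snai2 up from 5.12 ± 0.03 to 6.44 ± 0.23. The other largest rises were those of the secreted BMP and Wnt antagonist gene Sostdc1 (4.05), the collagen gene Col12a1 (3.82) and Akr1c14 (3.77) and Gpr165 (3.70). The other largest falls were those of the amino acid transporter gene Slc7a3 (-3.30), the fucosyltransferase gene Fut9 (-2.84) and Ccdc141 (-2.80), Mpzl2 (-2.62) and 4930550L24Rik (-2.49).

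Among the 23 fibroblast matrix genes, 20 rose and 3 did not pass (20 rose adjusted over the list alone). Examples were Fbln5 (3.42), Lox (3.22) and Col1a2 (2.68), at a median of 1.57 for the list (adjusted p = 1.5e-31 in limma's camera). Of 18 smooth muscle and SRF target genes, 13 rose and 5 did not pass (13 rose adjusted over the list alone). Cnn2 (2.78), Tagln (2.63) and Actg2 (2.51) were among them, and the median log2 change of the list was 1.14 (adjusted p = 1.1e-17 in limma's camera). Of 24 mesenchymal genes, 18 rose, 1 fell and 5 did not pass (18 rose and 1 fell adjusted over the list alone). Cdh11 (2.46) and S100a4 (1.42) were examples, and the list had a median log2 change of 0.86 (adjusted p = 1.6e-16 in limma's camera). Of 18 TGF-beta target genes, 14 rose and 4 did not pass (15 rose adjusted over the list alone). Examples were Ccn2 (2.89), Postn (2.69) and Edn1 (2.15), at a median of 0.96 for the list (adjusted p = 1.2e-16 in limma's camera). Of 23 BMP target genes, 17 rose and 6 did not pass (17 rose adjusted over the list alone). Bmper (1.55) and Atoh8 (1.45) were among them, and the median log2 change of the list was 0.57 (adjusted p = 3.2e-13 in limma's camera). Of 16 immediate early genes, 9 rose and 7 did not pass (10 rose adjusted over the list alone). Ccn1 (3.01) and Dusp1 (1.56) were examples, and the list had a median log2 change of 0.38 (adjusted p = 9.1e-08 in limma's camera).

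Of 25 cholesterol synthesis and SREBP target genes, 25 fell (25 fell adjusted over the list alone). Examples were Insig1 (-1.26), Dhcr7 (-1.25) and Lss (-1.08), at a median of -0.69 for the list (adjusted p = 3.5e-21 in limma's camera). Of 28 pluripotency genes, 1 rose, 9 fell and 18 did not pass (1 rose and 12 fell adjusted over the list alone). Sall4 (-1.74), Lin28b (-1.18) and Tet1 (-0.97) were among them, and the median log2 change of the list was -0.21 (adjusted p = 3.7e-05 in limma's camera). Of 24 epithelial genes, 2 rose, 8 fell and 14 did not pass (2 rose and 8 fell adjusted over the list alone). Elf3 (-1.26) and Krt8 (-0.80) were examples, and the list had a median log2 change of -0.18 (adjusted p = 0.0209 in limma's camera, and adjusted p = 0.102 with an estimated correlation). The epithelial call ended with the filter at the median and without ES medium replicate 2. Among the 24 hypoxia and glycolysis genes, 1 rose, 14 fell and 9 did not pass (1 rose and 17 fell adjusted over the list alone). Examples were Aldoc (-1.98) and Bnip3 (-1.30), at a median of -0.40 for the list (adjusted p = 2.7e-09 in limma's camera, and adjusted p = 0.0517 with an estimated correlation). Among the 31 cell cycle genes, 7 fell and 24 did not pass (1 rose and 8 fell adjusted over the list alone). Bub1 (-0.55) and Ccne1 (-0.50) were among them, and the median log2 change of the list was -0.17 (adjusted p = 0.00122 in limma's camera, and adjusted p = 0.263 with an estimated correlation). Among the 18 p53 and senescence genes, 5 rose and 13 did not pass (5 rose and 2 fell adjusted over the list alone). Fas (1.39) and Phlda3 (0.71) were examples, and the list had a median log2 change of 0.09 (adjusted p = 0.0484 in limma's camera, and adjusted p = 0.153 with an estimated correlation). This list call ended with quantile normalization, median centring, the array spread covariate or either filter, and without replicate 2 or 3 of SF1 or of ES medium. In all, 3862 genes were called in limma, 2004 higher and 1858 lower, with 593 at least 2-fold (452 higher and 141 lower). The adjusted p of Acta2 was 1.5e-13 and that of Nr0b1 2.4e-14 in limma.

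Against FBS, matrix genes were higher in ES medium, and epithelial genes and the mixed hypoxia and glycolysis genes were lower. The largest rises were those of the uncharacterised E330013P04Rik (3.54), the collagen crosslinking enzyme gene Lox (3.08) and Postn (3.00), and the largest falls those of the glycolytic enzyme gene Aldoc (-2.88) and Slc7a3 (-2.58) and Ndufa4l2 (-2.42). Postn was at 6.82 ± 0.42 in ES medium and 3.82 ± 0.30 in FBS, and Aldoc at 6.11 ± 0.14 and 8.99 ± 0.08 (SD, n = 3). Of 23 fibroblast matrix genes, 20 rose and 3 did not pass (21 rose adjusted over the list alone), with a median log2 change of 1.32 (adjusted p = 1.9e-31 in limma's camera). Among the 18 smooth muscle and SRF target genes, 12 rose and 6 did not pass (12 rose adjusted over the list alone), with a median log2 change of 0.57 (adjusted p = 4.3e-13 in limma's camera). Among the 24 mesenchymal genes, 16 rose and 8 did not pass (16 rose adjusted over the list alone), with a median log2 change of 0.34 (adjusted p = 3.0e-13 in limma's camera). Snai2 rose by 1.25 and Epcam fell by 0.69, while the arrays of Cdh1 overlapped, at 5.83 to 5.94 in ES medium and 5.69 to 5.89 in FBS. Among the 24 epithelial genes, 12 fell and 12 did not pass (12 fell adjusted over the list alone), with a median log2 change of -0.30 (adjusted p = 1.3e-07 in limma's camera). Of 24 hypoxia and glycolysis genes, 21 fell and 3 did not pass (23 fell adjusted over the list alone), with a median log2 change of -0.70 (adjusted p = 9.0e-23 in limma's camera). Among the 16 immediate early genes, 8 fell and 8 did not pass (8 fell adjusted over the list alone), with a median log2 change of -0.27 (adjusted p = 0.00122 in limma's camera). Among the 28 pluripotency genes, 8 fell and 20 did not pass (8 fell adjusted over the list alone), with a median log2 change of -0.12 (adjusted p = 0.00184 in limma's camera). Of 18 TGF-beta target genes, 13 rose and 1 fell (median log2 change 0.56, adjusted p = 1.3e-09 in limma's camera). Of 25 cholesterol synthesis and SREBP target genes, 1 rose and 14 fell (median -0.33, adjusted p = 1.1e-07 in limma's camera). Of 18 p53 and senescence genes, 9 fell and 9 did not pass (median -0.32, adjusted p = 2.4e-04 in limma's camera). Small nucleolar RNAs fell in 12 and rose in 3 of 51 genes (median log2 change -0.23). Limma called 3964 genes, 2226 higher and 1738 lower, with 268 at least 2-fold, and 7616 with array weights.

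**Figure D4:**
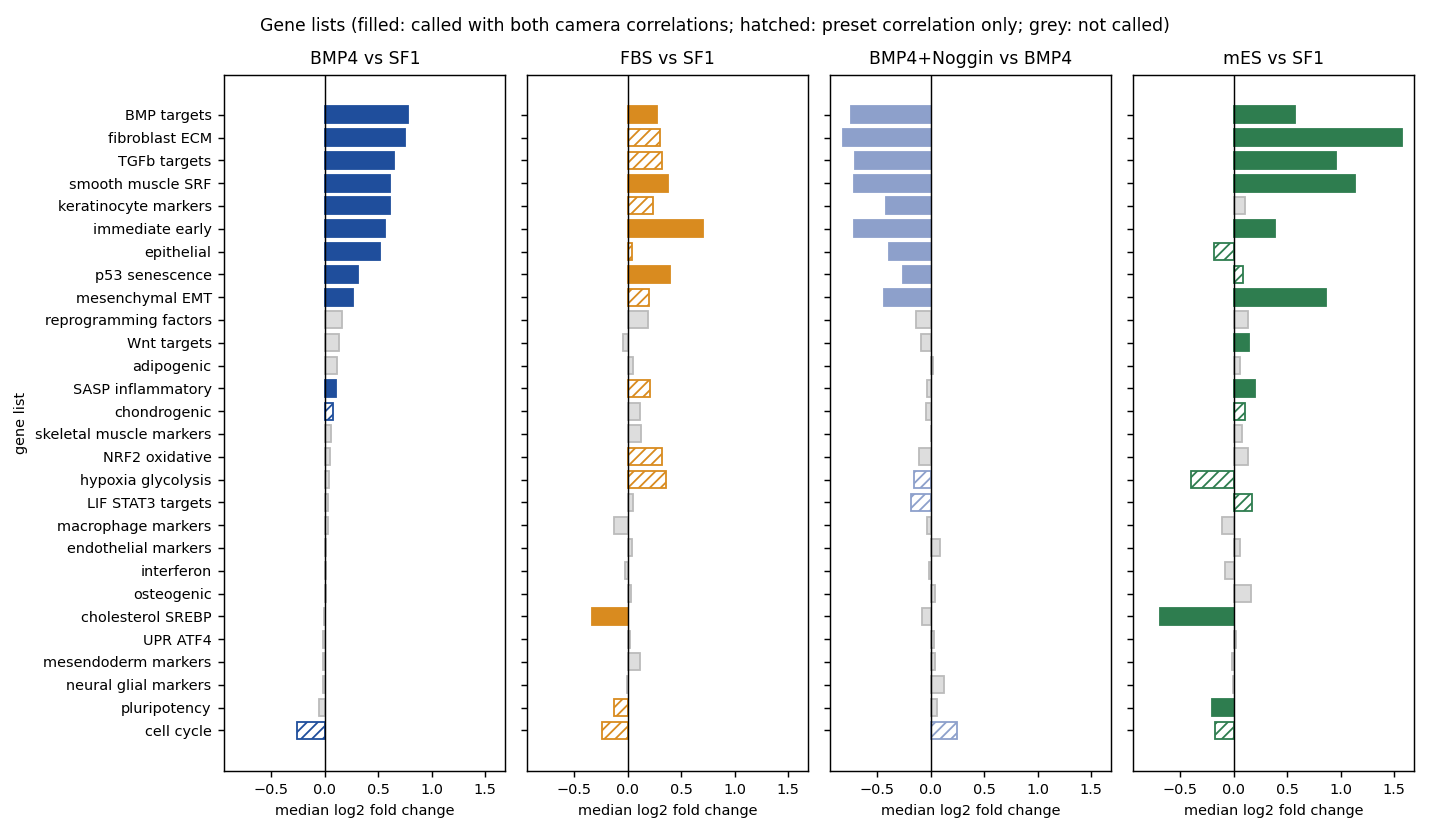
Median log2 fold change (x axis) of the members of each of 28 gene lists (y axis) in the 4 main comparisons; filled bars were called by camera with both the preset and the estimated correlation, hatched bars with the preset correlation alone, and grey bars were not called. The fibroblast matrix list is at 0.75 with BMP4, -0.82 when Noggin is added and 1.57 in ES medium.

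With the preset correlation limma's camera called 12 of 28 lists for BMP4, 15 for FBS, 12 for Noggin with BMP4 and 16 for ES medium. With the estimated correlation 10, 5, 9 and 10 of these held. For BMP4 plus Noggin with SF1, BMP4 with FBS and ES medium with FBS, 4, 11 and 16 lists were called, and 0, 4 and 11 held, the first with 3 lists at an unadjusted p under 0.05. Held in all comparisons of BMP4, FBS and ES medium with SF1 and of Noggin with BMP4 were the BMP target, smooth muscle and immediate early lists. The median, the mean and the test of a list differed in sign only for lists that were not called.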

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

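The tests of small nucleolar RNAs, of the array spread, of the matrix list and of the FBS replicates were chosen only after the results were seen. Among 7064 probes with several or no gene symbols, which the gene comparisons do not use, 73 were called with at least a 2-fold change in BMP4 against SF1, 58 higher and 15 lower. No symbol is listed for 33 of them, and 68 were called in the opposite direction when Noggin was added. Some of these probes share all their values, so the called ones hold 50 distinct sets of values, 35 higher and 15 lower, of which 47 turned back with Noggin.

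Between BMP4 plus Noggin and SF1 318 genes were called, with small nucleolar RNAs among the largest rises and 16 of 51 of them higher. With the interquartile range of each array as a covariate 79 genes were called, but the called genes kept their size, with a median log2 change in the direction of the call of 0.43 before and 0.39 with it and a median ratio of 0.932 (median SE 0.0879 and 0.0869). The calls lay near the threshold (median adjusted p = 0.0360 before and 0.0656 with it, in limma). A fall in the count by more than 1.5 times was the sign first set for the array value distribution as the cause, and it was met. Quantile normalization, which gives all arrays the same distribution of values, called 359 genes, 281 of them among the 318, while median centring called 128. With calls so near the threshold, counts that go both ways cannot tell whether the array value distribution is the cause. The sizes, measures chosen later, argue against it as the source of the log2 changes of the called genes, which were picked in the same fit. For the small nucleolar RNAs they argue against it too, with a median log2 change of 0.49 before and 0.50 with the covariate (median SE 0.127 and 0.129). Of these RNAs, 11 still rose. Short mRNAs of ribosomal proteins and the respiratory chain had a median log2 change of 0.13, with 0 of 10000 matched random lists as high. The random lists were matched on mean expression only and need not hold genes that move together. They thus cannot tell fuller recovery of short transcripts in the Noggin samples, which may have contributed, from a joint change of these genes. In all 7 comparisons the median of the short mRNAs had the sign of that of the small nucleolar RNAs, with 0.21 for Noggin against BMP4, -0.19 for BMP4 against FBS and -0.16 for ES medium against FBS. The comparisons share groups, and for ES medium against SF1 both medians were small (-0.016 for the short mRNAs and -0.023 for the small nucleolar RNAs). An effect of Noggin on these RNAs stays open, and the design holds no culture with Noggin alone to test it.

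Fibroblast matrix genes rose with BMP4, with 15 of 23 called higher. A larger share of unconverted fibroblasts would bring all their abundant transcripts. With BMP4 3 members, Col3a1, Dcn and Fbln2, were called lower with arrays that did not overlap, but only 2 stayed called without any 1 array, and 1703 of 19938 genes were called lower overall. These falls are too few to exclude such a share, which stays open. A shift of the normalization is argued against by random lists matched on mean expression, of which 0 of 10000 had a median log2 change of 0.374 or more (upper percentile of their medians 0.0786), against 0.75 for the list. Of the members that rose, 100% fell when Noggin was added. Of all genes called with BMP4, 79.1% turned back, as did 414 of the 415 changed at least 2-fold, and both comparisons use the BMP4 arrays. The share thus sets the list little apart. BMP signalling stays a candidate explanation, as a hypothesis found and tested on the same arrays. Another change in the makeup of the cultures, which Noggin could also turn back, stays open.

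FBS replicates 1 and 3 differed with an SD of 0.0787 over genes above the median, below the 0.130 to 0.241 of the other pairs of repeats. Whether they are 1 RNA hybridised 2 times or similar cultures cannot be told apart, since no known repeat hybridisation gives the level to compare with. No biological explanation was tested.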

How the results depend on the processing

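The array spread covariate and the FBS replicates taken as 1 sample were chosen only after the data were seen. The cause of the changes below was not tested unless the alternative itself gives it. Over all alternatives 2892 values of named genes kept their direction and their side of the threshold, 44 no longer passed and 0 newly passed. For lists these numbers were 1533, 44 and 15, and no called direction turned. Calls with at least a 2-fold change numbered 415, 248, 511 and 593 for BMP4 with SF1, FBS with SF1, Noggin with BMP4 and ES medium with SF1, and 2, 144 and 268 for BMP4 plus Noggin with SF1, BMP4 with FBS and ES medium with FBS. At an adjusted p below 0.01 in limma they numbered, in the same order, 2175, 2628, 3049, 2573, 13, 1624 and 2429, since both are stricter. The count for BMP4 plus Noggin with SF1 moved most. It stayed within 1.5 times at 359 with quantile normalization, 289 with the mean over probes and 301 with array weights. It was 79 with the array spread covariate, 128 with median centring, 971 and 518 with filters at the median and the 25th percentile, 873 with an intensity trend and robust spread, 630 with no moderation, 609 with every probe and 0 with only these groups in limma (2509 at an unadjusted p under 0.05). Array weights gave 6482 for BMP4 with FBS and 7616 for ES medium with FBS. FBS replicates 1 and 3 as 1 sample gave 3199, 2076 and 2919 for FBS with SF1, BMP4 with FBS and ES medium with FBS, with fewer samples. Leaving out 1 array at a time gave 2717 to 3127 genes for BMP4 with SF1, 3178 to 3621 for FBS with SF1, 3723 to 4317 for Noggin with BMP4, 3106 to 3518 for ES medium with SF1, 15 to 232 for BMP4 plus Noggin with SF1, 2041 to 2624 for BMP4 with FBS and 2900 to 4042 for ES medium with FBS. Past 1.5 times were those without Noggin replicates 1 (15) and 3 (19) or SF1 replicates 1, 2 and 3 (33, 26 and 70) for BMP4 plus Noggin with SF1, and without BMP4 replicate 2 (2096) or FBS replicate 3 (2041) for BMP4 with FBS. The overlap of BMP4 and FBS calls ran from 1569 to 1756 and the genes turned back by Noggin from 2161 to 2606. The correlation across genes of BMP4 minus BMP4 plus Noggin with FBS minus SF1 was 0.585 and 0.545 with the filters, against 0.510 in the main fit. With an estimated correlation camera called 5 lists for FBS, 10 for ES medium, 0 for BMP4 plus Noggin with SF1 (3 at an unadjusted p under 0.05) and 4 for BMP4 with FBS. With the filter at the median 0 were called for BMP4 plus Noggin with SF1 (4 unadjusted). Without 1 array there were 2 to 5, the lowest without SF1 replicate 1 (2). With the replicate number as a replicate block, limma called 3345, 4010, 4556, 3689, 98, 2929 and 3746 genes in the order above, and Bex4 and Hoxb2 were no longer called for BMP4 plus Noggin with SF1. The numbers do not pair the arrays, since 8 of 30 same-numbered pairs had a residual correlation over 0.1 and their mean was -0.0129. Without detection calls, nothing shows whether genes near or below the median of 5.37 lie above background. Examples are Sox2 and Nanog, and Esrp1 in SF1 (3.99 to 4.06). The size of a log2 change from such a level, and its rank, are thus uncertain.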

Other observations

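Of 16 Wnt target genes, in ES medium against SF1, 6 rose and 10 did not pass (6 rose and 1 fell adjusted over the list alone). The Wnt modulator gene Sfrp2 (2.25), the stem cell receptor gene Lgr5 (1.86) and Dkk2 (1.61) and Ccnd1 (1.30) were among them, and the median log2 change of the list was 0.15 (adjusted p = 2.5e-04 in limma's camera). Among the 16 Wnt target genes, in ES medium against FBS, 7 rose and 9 did not pass (9 rose adjusted over the list alone), with a median log2 change of 0.28 (adjusted p = 5.5e-06 in limma's camera). Of 14 chondrogenic genes, in ES medium against SF1, 5 rose, 1 fell and 8 did not pass (5 rose and 1 fell adjusted over the list alone). Examples were the cartilage collagen genes Col11a1 (1.37) and Col2a1 (1.30), at a median of 0.11 for the list (adjusted p = 0.00414 in limma's camera, and adjusted p = 0.171 with an estimated correlation). The list call ended without SF1 replicate 1, with the median change then negative. Among the 14 chondrogenic genes, with BMP4 against SF1, 4 rose and 10 did not pass (4 rose adjusted over the list alone). The aggrecan gene Acan (1.47) and Hapln1 (0.66) were among them, and the median log2 change of the list was 0.08 (adjusted p = 0.0133 in limma's camera, and adjusted p = 0.267 with an estimated correlation). This call ended with the filter at the median and without SF1 replicate 1, which turned the median change negative. Osteogenic genes were called in the main fit for ES medium against FBS alone, and against SF1 only without ES medium replicate 1. Of 10 osteogenic genes, 3 rose and 7 did not pass (3 rose adjusted over the list alone), with a median log2 change of 0.22 (adjusted p = 0.0199 in limma's camera, and adjusted p = 0.0512 with an estimated correlation). Adipogenic genes were not called in any comparison (adjusted p 0.257 to 0.948 in limma's camera), although Lpl, a lipoprotein lipase gene, fell in ES medium (-1.69) and the fatty acid uptake gene Cd36 rose with BMP4 (1.25).

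Of 22 inflammatory secretion genes, with BMP4 against SF1, 8 rose, 1 fell and 13 did not pass (8 rose and 1 fell adjusted over the list alone). Examples were the adhesion gene Vcam1 (1.70) and Ptgs2 (1.61), at a median of 0.10 for the list (adjusted p = 0.0191 in limma's camera). Among the 22 inflammatory secretion genes, in ES medium against SF1, 9 rose, 3 fell and 10 did not pass (9 rose and 3 fell adjusted over the list alone). Csf1 (1.21) and Ccl2 (1.16) were among them, and the median log2 change of the list was 0.20 (adjusted p = 0.0127 in limma's camera). Of 22 inflammatory secretion genes, with FBS against SF1, 6 rose, 1 fell and 15 did not pass (6 rose and 1 fell adjusted over the list alone). Ptgs2 (2.37) and Nfkbia (0.75) were examples, and the list had a median log2 change of 0.21 (adjusted p = 0.0208 in limma's camera, and adjusted p = 0.0714 with an estimated correlation). Of 15 NRF2 target genes, which respond to oxidative stress, with FBS against SF1, 6 rose, 1 fell and 8 did not pass (9 rose and 2 fell adjusted over the list alone). Examples were Nqo1 (1.46), Gsta4 (1.15) and Srxn1 (0.85), at a median of 0.32 for the list (adjusted p = 0.00134 in limma's camera, and adjusted p = 0.0835 with an estimated correlation). Of 15 LIF and STAT3 target genes, in ES medium against SF1, 3 rose, 1 fell and 11 did not pass (7 rose and 3 fell adjusted over the list alone). The receptor gene Osmr (2.24) and Cebpd (1.55) were among them, and the median log2 change of the list was 0.17 (adjusted p = 0.0141 in limma's camera, and adjusted p = 0.171 with an estimated correlation). The list call ended without SF1 replicate 3. Among the 15 LIF and STAT3 target genes, with Noggin added to BMP4, 5 fell and 10 did not pass (5 fell adjusted over the list alone). Cebpd (-1.08) and Osmr (-0.76) were examples, and the list had a median log2 change of -0.18 (adjusted p = 0.0197 in limma's camera, and adjusted p = 0.233 with an estimated correlation). This call ended with quantile normalization, either filter and without BMP4 replicate 1.

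Lists not called in any comparison by limma's camera were the interferon response (adjusted p 0.233 to 0.956), with Bst2 lower in ES medium (-0.77), and the unfolded protein response and ATF4 (adjusted p 0.818 to 0.974), with the cystine transporter gene Slc7a11 higher with BMP4 (1.24). Markers of macrophages (adjusted p 0.114 to 0.962 in limma's camera), endothelium (adjusted p 0.223 to 0.761), skeletal muscle (adjusted p 0.155 to 0.781), neural and glial cells (adjusted p 0.506 to 0.974) and mesendoderm (adjusted p 0.275 to 0.890) were not called in the main fit either, although macrophage markers were called lower in ES medium against SF1 without ES medium replicate 1. Single members changed with BMP4, with Laptm5 (-1.81), Tek (-0.57) and Elavl4 (-0.66) lower and Pax3 (1.09) and Nes (0.69) higher. Of the mesendoderm markers none passed with BMP4 in limma (0 at an unadjusted p under 0.05). Gata6 was at 5.33 ± 0.09 with BMP4 and 5.04 ± 0.05 in SF1 (adjusted p = 0.203 in limma), and Gsc at 5.23 ± 0.29 and 4.95 ± 0.29 (adjusted p = 0.262).

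Groups of 3 arrays allow 10 splits of the 6 arrays of a comparison, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, called as many genes in limma. The other splits mix arrays of both media in each group, so a difference between media widens their spread and lowers their counts. For BMP4 plus Noggin with SF1, the real split called 0 genes in a limma fit of these arrays alone. The real counts were 3545, 4229, 4772 and 3862 for BMP4 with SF1, FBS with SF1, Noggin with BMP4 and ES medium with SF1, and 318, 3155 and 3964 for BMP4 plus Noggin with SF1, BMP4 with FBS and ES medium with FBS. The highest of the other splits called 1 gene for ES medium with FBS and 0 for each of the other comparisons. At an unadjusted p under 0.05 in limma they had at most 1492, 1968, 2017, 2166, 2278, 1487 and 1320 genes in the same order. The real groups had 5645, 6275, 6816, 5782, 3356, 5533 and 6120 at that p in the fit of all 15 arrays.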
